A study of Mus musculus with 32 samples.

How the data were processed

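RNA was sequenced from OG2X129 mouse embryonic fibroblasts in chemical reprogramming, from induced pluripotent stem cell (iPSC) lines derived with CD3254 (CD) or DMSO, from embryonic fibroblasts (MEF) and from R1 embryonic stem cells. DMSP in iPSC labels is taken for DMSO. There are 32 libraries in 16 groups of 2. The reprogramming tables compare CD with DMSO, Rxra overexpression (Rxra OE) with its control (CTR), and knockdown of Exosc3 (shE3) with a control hairpin (shCTR). A further table follows CD and DMSO cultures over 0, 4 and 8 h of actinomycin D. The labels do not say whether replicates are separate cultures, so every p-value measures only the spread between samples.

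Per the submitters' processing notes, the tools were fastp 0.20.1, HISAT2 2.1.0 and StringTie 2.0 and the build mm10; options and order are not given in the sources used here. The CD, Rxra OE, shE3 and iPSC tables hold TPM as deposited by the authors, and their sequencing depth is not given by the values. The unit of the actinomycin D table is not named per the file headers; its deposited signal was checked to be CPM, reads scaled to a fixed total. Dividing each value by the smallest step of its library gave whole reads, within a tolerance of 0.001, for 100 percent of values in the 0 h libraries and 99.996 percent in each of the others, where MMVL30-int is the exception. The recovered depth is 15382821 to 24186485 reads per library. That table also lists 1146 repeat families, each under 2 names and used once, and 92 ERCC spike-ins. Each table lists 55401 genes, of which 55141 identifiers were named from GENCODE M21 (GRCm38, mm10) and 260 stayed without a name. On that assembly Rxra lies at chromosome 2, 27676440 to 27762957, plus strand, and Exosc3 at chromosome 4, 45316613 to 45342732, minus strand.

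Mitochondrial genes take 50.9 to 62 percent of TPM in the CD and Rxra OE tables, 11.8 to 15.5 in the shE3 table, 7.46 to 17.4 in the iPSC table and 4.93 to 9.29 percent of CPM in the actinomycin D table. Pearson correlations between the 2 libraries of a group, across genes, run from 0.968 (CD 0 h) to 0.995; genes are not independent replicates.

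Genes with a value of 1 or more in at least 2 libraries of a table were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with an eBayes trend, 2-sided, and Benjamini-Hochberg adjusted p under 0.05 over genes; repeat families were adjusted apart. Decay was tested as 8 h against 0 h within each arm and as the difference between arms. Where the median gene moved by more than 0.1 on the log2 scale, changes are given relative to it, from libraries rescaled by the median ratio to the gene-wise geometric mean (CD, Rxra OE, the 0 h comparison, both 8 h contrasts and DMSO iPSC against R1); named genes said to rise or fall there passed in both scalings, levels are as deposited, and counts are given first as deposited. Log2 changes carry their SE and levels their SD. For genes listed at 0 in both libraries of a group, how the quantification assigned reads was not tested.

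The 23 fixed gene lists, named as they appear below, were tested by counting members past the threshold over all genes and adjusted over the list alone, and with camera at a preset inter-gene correlation of 0.01, adjusted over lists; the count adjusted over the list alone is left out where it differs from the first by at most 1 gene, and a list's count relative to the median gene where it differs by at most 2. Camera with an estimated correlation stands beside it for lists that pass. Overlaps of calls were tested with 2-sided Fisher exact tests on genes tested in both tables. RNAs called higher in shE3 and, chosen after seeing the data, those called lower were tested as sets in the difference of decay. On recovered reads, edgeR 4.0.16 and DESeq2 1.42.0 were run beside limma. Figures and joins used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

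Named genes follow a rule: Rxra and Exosc3 always; per direction the 6 largest changes (4 in the actinomycin D and R1 comparisons) past the threshold without overlap between libraries and with a mean of at least 5 in the higher group; up to 3 members of each list with the smallest p, or the member with the highest mean where none passed; and Pou5f1, Nanog and Sox2 in the iPSC table. Members were left out to keep each comparison near 30 genes, after their values were seen, mostly those that depend on 1 library, and a few that the rule selects are not reported here. The comparisons, tests, lists, this rule and the first set of alternatives were chosen before the data were examined.

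The tests were run on data simulated from each table, with 100 genes planted per size. For planted log2 changes of 1 and 2, limma recovered 100 and 100 genes in the CD design, 99 and 100 in Rxra OE, 100 and 100 in shE3, 64 and 96 at 0 h, 19 and 91 in the difference of decay and 79 and 99 between iPSC lines; edgeR recovered 11 and 75 and DESeq2 25 and 92 in the difference of decay. There limma called 7 unchanged genes, edgeR 5 and DESeq2 22. A planted set of 50 genes shifted by 0.5 was called by camera at the preset correlation in all 6 designs. With an estimated one it was called in 3, none of them CD, Rxra OE or shE3.

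Alternatives covered the pseudocount (0.1), the filter (none, or 5), a fold change of at least 2, quantile normalization, median ratio rescaling, eBayes without trend, the replicate number as a block and each library left out in turn. Alternatives chosen after seeing the data were rescaling to nuclear coding and lncRNA genes, crossed replicate numbers as a block, spike-in scaling, the count tools and the exchange of 2 MMVL30-int time points. The 4 h time point is given only for the difference of decay and MMVL30-int.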

Results

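With CD3254, fibroblasts in chemical reprogramming carried more RNA of epithelial, extraembryonic endoderm-like (XEN-like), pluripotency and cell cycle genes and less of fibroblast genes (CD against DMSO, n = 2 libraries per group, mean ± SD). These lists pass camera at the preset correlation, and none does with estimated correlation (adjusted p of 0.393 to 0.658). Gata4, an endoderm transcription factor, stood at 136 ± 2.63 against 29.4 ± 0.277 TPM, a log2 change of 1.97 ± 0.04 (SE) relative to the median gene, adjusted p = 2.41e-05. Krt8, a keratin of simple epithelia, stood at 212 ± 11.8 against 48.9 ± 2.87 TPM (1.88 ± 0.04, adjusted p = 2.46e-05), and the collagen gene Col3a1 fell from 239 ± 6.82 to 104 ± 5.72 TPM (-1.40 ± 0.04, adjusted p = 2.85e-05). Rxra, which encodes the receptor that CD3254 binds, was lower with CD (8.85 ± 0.577 against 11.5 ± 0.687 TPM): -0.34 ± 0.08 as deposited and -0.53 ± 0.06 relative to the median gene (adjusted p = 0.0013). Exosc3, a subunit of the RNA exosome, rose (19.2 ± 0.688 against 9.96 ± 0.965 TPM), by 0.89 ± 0.08 as deposited and 0.69 ± 0.06 relative to the median gene (adjusted p = 0.000536).

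The rises ranged over several cell states. Cyp26a1, a retinoic acid hydroxylase, reached 417 ± 5.67 against 86.5 ± 3.88 TPM (2.05 ± 0.03), and 2 further genes of the list of targets of RXR and its partner receptors rose with it: Apoe (2.00 ± 0.05) and Fabp3 (2.46 ± 0.05). The list as a whole went both ways (11 rose and 11 fell of 25, camera adjusted p = 0.193). Car4, a carbonic anhydrase, had the steepest rise among the named genes (2.97 ± 0.05, 64.5 against 6.31 TPM), followed by Gkn3 (2.94 ± 0.14), Myl3 (2.81 ± 0.10), Sept4 (2.77 ± 0.17), Pglyrp1 (2.59 ± 0.06) and Myl7 (2.52 ± 0.06). XEN-like genes moved nearly together, with Gata4 beside Col4a1 (1.80 ± 0.04) and Pth1r (1.84 ± 0.04). Of 21 XEN-like genes, 19 rose, 1 fell and 1 did not pass (camera adjusted p = 2.12e-06, or 0.658 with estimated correlation). Epithelial genes did the same: Krt19 (1.77 ± 0.04) and Epcam (1.44 ± 0.05) rose with Krt8. Of 20 tested, 19 rose, 1 fell and 0 did not pass (camera adjusted p = 8.55e-06, or 0.513 with estimated correlation). Pluripotency genes rose, with Tdh (2.48 ± 0.04), Mybl2 (1.67 ± 0.05) and Klf4 (1.38 ± 0.04). Of 15 tested, 13 rose, 1 fell and 1 did not pass (camera adjusted p = 0.000326, or 0.393 with estimated correlation). Pou5f1 and Nanog were below 1 TPM throughout, and Sox2 was lower (0.58 and 0.64 against 1.3 and 1.2). Cell cycle genes rose in 31 of 32 cases (31 and 1 adjusted over the list alone; camera adjusted p = 2.60e-08, or 0.393 with estimated correlation), among them Ccnb1 (1.48 ± 0.09), Ccnb2 (1.46 ± 0.07) and Ccna2 (1.24 ± 0.07).

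Falls included fibroblast, cholesterol synthesis and p53 genes. Fibroblast genes fell, Cdh11 (-1.17 ± 0.03) and Col1a2 (-1.12 ± 0.03) after Col3a1. Of 33 fibroblast genes, 3 rose, 24 fell and 6 did not pass (camera adjusted p = 1.27e-09, or 0.393 with estimated correlation). Cholesterol synthesis genes fell, including Cyp51 (-1.06 ± 0.04) and Hsd17b7 (-0.93 ± 0.05). Of 24 tested, 2 rose, 18 fell and 4 did not pass (camera adjusted p = 3.58e-07, or 0.393 with estimated correlation). The p53 and senescence genes fell, among them Igfbp5 (-1.44 ± 0.03), Pmaip1 (-1.12 ± 0.03) and Igfbp3 (-1.06 ± 0.03), of which Igfbp3 encodes a secreted growth factor binding protein at 359.6 ± 5.22 against 648 ± 21.3 TPM. Of 26 tested, 4 rose, 18 fell and 4 did not pass (camera adjusted p = 1.21e-06, or 0.393 with estimated correlation). Inflammatory mediators fell more often than they rose: the chemokine gene Ccl8 stood at 344 ± 2.28 against 725 ± 8.83 TPM (-1.28 ± 0.03) and the protease gene Mmp3 changed by -1.26 ± 0.05, while the cytokine gene Lif rose (0.86 ± 0.06). Of 26 tested, 6 rose, 13 fell and 7 did not pass, 3 and 16 relative to the median gene (camera adjusted p = 0.00131, or 0.393 with estimated correlation). Larger falls than these were seen in Pcdh10 (-2.59 ± 0.06), Lrat, a retinol acyltransferase (-2.49 ± 0.08), Ass1 (-2.35 ± 0.07) and Adamts8 (-2.15 ± 0.06). Apart from these, Kctd12 was listed at 0 in both CD libraries and at 18.5 and 18.6 TPM in the DMSO libraries, and the microRNA gene Mir124a-3 at 0 and at 129 and 177. Whether reads of these 2 genes were assigned elsewhere in some libraries was not tested.

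Interferon-stimulated genes rose with CD, led by Isg15 (1.87 ± 0.09) and Ifi27l2a (1.38 ± 0.11), whereas Ifit2 fell (-1.42 ± 0.07). Of 27 tested, 23 rose, 1 fell and 3 did not pass, 17 and 2 relative to the median gene (camera adjusted p = 0.00203, or 0.393 with estimated correlation). Of the RNA exosome subunits and cofactors, Exosc8 (1.23 ± 0.05) and Exosc7 (0.73 ± 0.06) rose with Exosc3, but the list did not pass camera (16 rose and 2 fell of 27, 12 and 4 relative to the median gene, camera adjusted p = 0.0648). Long-lived mRNAs, most of them for ribosomal proteins and housekeeping enzymes, also rose, as in Rpl4 (0.48 ± 0.03). Of 35 long-lived mRNAs, 26 rose, 2 fell and 7 did not pass, 17 and 8 relative to the median gene (camera adjusted p = 0.00436, or 0.737 with estimated correlation). The remaining lists did not pass camera. Imprinted genes (11 rose and 6 fell of 25, camera adjusted p = 0.523) included Dlk1 (2.36 ± 0.06) and Peg10 (1.64 ± 0.04). The others were short-lived mRNAs (18 rose and 7 fell of 39, 13 and 13 relative to the median gene, camera adjusted p = 0.696), snoRNA host genes (10 rose and 2 fell of 14, camera adjusted p = 0.0913), nucleic acid sensing (9 rose and 0 fell of 14, 5 and 1 relative to the median gene, camera adjusted p = 0.0913) and 2-cell-like genes (0 rose and 1 fell of 2, camera adjusted p = 0.491). Markers of other cell types were few among the tested genes and went both ways: neural (2 rose and 5 fell of 9, camera adjusted p = 0.0648), keratinocyte (2 rose and 2 fell of 6, camera adjusted p = 0.291), and muscle (4 rose and 1 fell of 6, camera adjusted p = 0.56). So did endothelial (4 rose and 2 fell of 6, camera adjusted p = 0.642), adipocyte (4 rose and 1 fell of 6, camera adjusted p = 0.645) and macrophage markers (2 rose and 1 fell of 3, camera adjusted p = 0.877). In all, 5612 genes rose and 2534 fell of 13006 tested (68.9 percent of calls upward). The median gene was itself 0.18 higher on the log2 scale; relative to it 3969 rose and 4051 fell (49.5 percent upward).

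**Figure D1:**
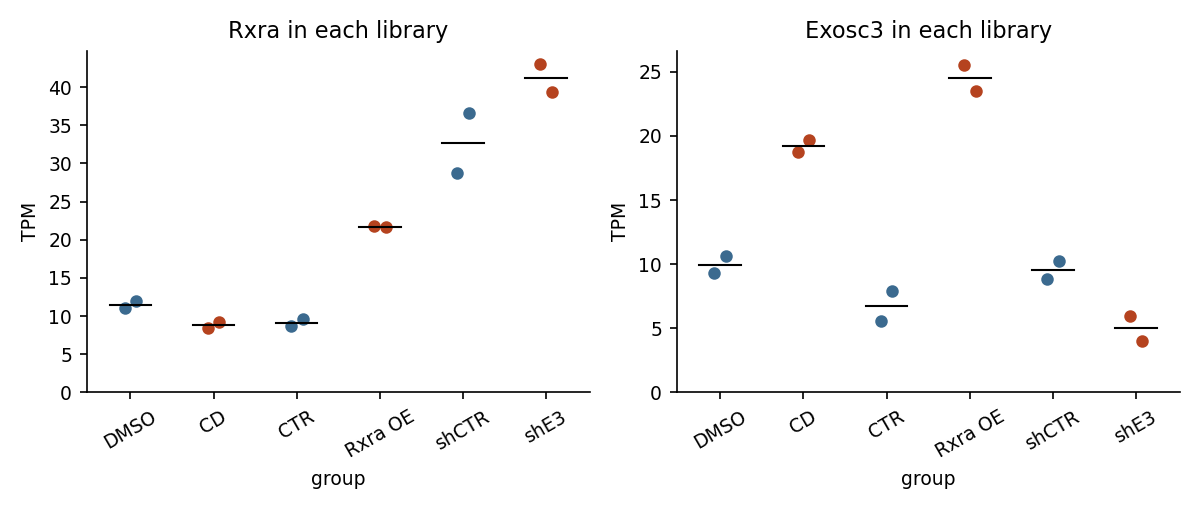
Rxra and Exosc3 in TPM (vertical axis) in each library (points) of the 6 groups of the 3 reprogramming tables (horizontal axis), with a line at the mean of n = 2. Rxra is lower with CD (8.85 against 11.5 TPM) and higher with Rxra OE (21.7 against 9.14 TPM); Exosc3 is higher with both and lower with shE3 (4.99 against 9.54 TPM).

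With overexpression of Rxra, epithelial, XEN-like, pluripotency and cell cycle genes were higher and fibroblast genes lower (Rxra OE against CTR, n = 2 per group). None of these lists passes camera with estimated correlation (adjusted p of 0.738 to 0.792). Rxra itself stood at 21.7 ± 0.0365 against 9.14 ± 0.611 TPM, 1.17 ± 0.09 higher as deposited (adjusted p = 4.51e-05) and 0.47 ± 0.06 higher relative to the median gene (adjusted p = 0.000957). Exosc3 stood at 24.5 ± 1.44 against 6.73 ± 1.69 TPM (1.74 ± 0.15 as deposited, 1.05 ± 0.12 relative to the median gene, adjusted p = 0.00065). Krt19, an epithelial keratin, reached 229 ± 8.29 against 24.4 ± 1.27 TPM (2.44 ± 0.05, adjusted p = 7.88e-06), and Col1a1, the main fibrillar collagen gene of fibroblasts, dropped to 68.2 ± 3.24 against 306 ± 23.9 TPM (-2.89 ± 0.06, adjusted p = 7.88e-06).

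The largest rises were in Gbx2 (3.69 ± 0.08), Grrp1 (3.44 ± 0.11), Mdk (3.31 ± 0.09), Myl3 (3.21 ± 0.11) and Cryaa (3.13 ± 0.08); Gbx2 encodes a homeobox factor and Mdk the growth factor midkine, at 374 ± 37.8 against 21.8 ± 3.07 TPM. Mir124a-3 was listed at 0 in both CTR libraries and at 962 and 826 TPM in the Rxra OE libraries, the reverse of its values with CD and with the same doubt about the assignment of its reads. Cyp26a1 again rose (521 ± 12.5 against 47.4 ± 4.38 TPM, 2.69 ± 0.05), though the list of RXR partner targets leaned down. Of 23 RXR partner targets, 10 rose, 11 fell and 2 did not pass, 7 and 13 relative to the median gene (camera adjusted p = 0.00928, or 0.792 with estimated correlation). Rises covered epithelial genes, with Krt18 (2.19 ± 0.05) and Cldn7 (1.69 ± 0.07), XEN-like genes, with Foxa2 (2.13 ± 0.07) and Gata4 (2.02 ± 0.05), pluripotency genes, with Lin28a (2.00 ± 0.09) and Tdh (1.93 ± 0.07), and cell cycle genes, with Birc5 (1.83 ± 0.06), Mcm5 (1.72 ± 0.07) and Mcm6 (1.66 ± 0.06). Of 20 epithelial genes, 19 rose, 0 fell and 1 did not pass (camera adjusted p = 0.000239, or 0.792 with estimated correlation). Of 21 XEN-like genes, 20 rose, 0 fell and 1 did not pass, 16 and 2 relative to the median gene (camera adjusted p = 0.00233, or 0.792 with estimated correlation). Of 13 pluripotency genes, 12 rose, 0 fell and 1 did not pass (camera adjusted p = 0.0106, or 0.738 with estimated correlation). Pou5f1, Nanog and Sox2 were below 1 TPM in every library, with Sox2 at 0.311 and 0.300 against 0.577 and 0.546. Of 32 cell cycle genes, 31 rose, 0 fell and 1 did not pass (camera adjusted p = 3.64e-06, or 0.738 with estimated correlation). RNA exosome genes rose as a list, with Exosc8 (1.24 ± 0.09), Exosc7 (1.22 ± 0.07) and Exosc5 (0.88 ± 0.07) beside Exosc3. Of 27 RNA exosome genes, 24 rose, 0 fell and 3 did not pass, 13 and 4 relative to the median gene (camera adjusted p = 0.0408, or 0.792 with estimated correlation). Imprinted genes, with Meg3 (2.93 ± 0.07) and Rian (1.80 ± 0.05), rose in 21 of 26 cases (21 and 4 adjusted over the list alone) without passing camera (adjusted p = 0.185), as did snoRNA host genes (13 rose and 1 fell of 14, camera adjusted p = 0.0609), led by Snhg20 (2.13 ± 0.09). Markers of some other cell types rose more often than they fell, without passing camera: endothelial (5 rose and 2 fell of 7, camera adjusted p = 0.79; Flt1 2.09 ± 0.07), keratinocyte (7 rose and 2 fell of 11, camera adjusted p = 0.976; Lamb3 1.91 ± 0.09) and muscle (6 rose and 1 fell of 10, 6 and 4 relative to the median gene, camera adjusted p = 0.98; Tnnt3 1.88 ± 0.14, Myod1 1.47 ± 0.10).

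The steepest falls included Masp1 (-3.37 ± 0.05), Pcsk6 (-3.31 ± 0.07), Slit3 (-3.26 ± 0.07), Ptgs1 (-3.25 ± 0.13) and Grem1 (-3.18 ± 0.09). Ahnak2 was listed at 1.15 ± 0.114 against 1891 ± 288 TPM (-10.34 ± 0.14), but whether the quantification assigned its reads elsewhere in the Rxra OE libraries was not tested. Fibroblast genes fell together: Prrx1 (-2.49 ± 0.07) and Lum (-2.36 ± 0.07) followed Col1a1. Of 33 fibroblast genes, 3 rose, 30 fell and 0 did not pass, 0 and 30 relative to the median gene (camera adjusted p = 9.27e-25, or 0.738 with estimated correlation). The same held for p53 and senescence genes, with Cdkn2b (-2.03 ± 0.06), Pmaip1 (-1.97 ± 0.05) and Ccng1 (-1.94 ± 0.08), and inflammatory mediators, with Ccl11 (-2.91 ± 0.07), Ptgs2 (-2.75 ± 0.10) and Mmp3 (-2.50 ± 0.09). Of 26 p53 and senescence genes, 6 rose, 15 fell and 5 did not pass, 0 and 22 relative to the median gene (camera adjusted p = 5.60e-08, or 0.738 with estimated correlation). Of 24 inflammatory mediators, 5 rose, 13 fell and 6 did not pass, 2 and 19 relative to the median gene (camera adjusted p = 1.03e-07, or 0.738 with estimated correlation). Lyz2, a lysozyme gene of macrophages, fell with them (-1.59 ± 0.08, 4.17 against 9.06 TPM), as did the interferon-stimulated gene Ifit2 (-2.65 ± 0.07). The direction of some lists depends on the scaling, among them interferon-stimulated genes (5 rose and 3 fell of 15, 3 and 7 relative to the median gene, camera adjusted p = 0.0933), short-lived mRNAs (22 rose and 7 fell of 39, 10 and 20 relative to the median gene, camera adjusted p = 0.548) and cholesterol synthesis genes (10 rose and 5 fell of 24, 2 and 18 relative to the median gene, camera adjusted p = 0.0894). In all, 9123 genes rose and 1862 fell of 13305 tested (83 percent of calls upward), over a median gene 0.62 higher; relative to it 4667 rose and 4718 fell, and 906 genes were called upward as deposited and downward relative to the median.

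With knockdown of Exosc3, cell cycle, XEN-like, epithelial and pluripotency genes were lower (shE3 against shCTR, n = 2 per group). None of these lists passes camera with estimated correlation (adjusted p of 0.526 for each). Without a filter 2 genes are called, and of the 38 genes named for this comparison as passing, 37 no longer pass, Exosc3 among them (adjusted p = 0.184). Only Rn7s2 still passes. Exosc3 itself fell from 9.54 ± 0.96 to 4.99 ± 1.39 TPM (-0.83 ± 0.17, adjusted p = 0.00767); without shCTR replicate 2 it no longer passed (-0.74). Epcam, an epithelial adhesion gene, dropped to 11.5 ± 0.82 against 51.2 ± 3.06 TPM (-2.07 ± 0.11, adjusted p = 3.03e-06) and Gata4 to 13.3 ± 0.696 against 50.5 ± 3.83 TPM (-1.85 ± 0.11, adjusted p = 5.09e-06). Lyz2 rose to 338 ± 1.27 against 139.9 ± 19.7 TPM (1.27 ± 0.11, adjusted p = 3.39e-05). Rxra did not pass (41.2 ± 2.56 against 32.7 ± 5.51 TPM, 0.34 ± 0.13, adjusted p = 0.0927) as deposited. It passed relative to the median gene (0.38 ± 0.08, adjusted p = 0.0228), with quantile normalization (0.35), with a filter at 5 (0.34) and without shCTR replicate 2 (0.50).

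Cell cycle genes fell in 31 of 32 cases (1 and 31 adjusted over the list alone; camera adjusted p = 5.00e-22, or 0.526 with estimated correlation), with Top2a (-1.60 ± 0.11), Ccna2 (-1.57 ± 0.12) and Mcm6 (-1.53 ± 0.12). XEN-like genes fell with Srgn (-1.86 ± 0.10) and Cited1 (-1.82 ± 0.10) beside Gata4, epithelial genes with Cldn7 (-1.99 ± 0.15) and Krt8 (-1.87 ± 0.11), and pluripotency genes with Lin28a (-2.21 ± 0.14), Tdh (-2.12 ± 0.12) and Sall4 (-1.74 ± 0.16). Of 21 XEN-like genes, 0 rose, 17 fell and 4 did not pass, 0 and 20 adjusted over the list alone (camera adjusted p = 1.08e-18, or 0.526 with estimated correlation). Of 20 epithelial genes, 0 rose, 16 fell and 4 did not pass (camera adjusted p = 4.65e-14, or 0.526 with estimated correlation). Of 14 pluripotency genes, 1 rose, 11 fell and 2 did not pass (camera adjusted p = 2.61e-07, or 0.526 with estimated correlation). Cyp26a1 (-1.54 ± 0.10) and Fabp3 (-1.43 ± 0.12) fell while the scavenger receptor gene Cd36 rose (1.22 ± 0.14), in a list of RXR partner targets that moved both ways (3 rose and 9 fell of 26, 9 and 9 relative to the median gene, camera adjusted p = 0.482). Among imprinted genes falls outnumbered rises, with the abundant noncoding H19 (1311 ± 7.76 against 2855 ± 220.5 TPM, -1.12 ± 0.11), Meg3 (-1.51 ± 0.11) and Peg10 (-1.36 ± 0.10). Of 27 imprinted genes, 1 rose, 11 fell and 15 did not pass, 1 and 16 adjusted over the list alone, 2 and 14 relative to the median gene (camera adjusted p = 3.80e-05, or 0.749 with estimated correlation). Of snoRNA host genes some fell, including Snhg12 (-1.01 ± 0.13), Snhg5 (-0.91 ± 0.12) and Gas5 (-0.86 ± 0.10). Of 16 snoRNA host genes, 0 rose, 8 fell and 8 did not pass, 0 and 10 adjusted over the list alone (camera adjusted p = 0.000106, or 0.555 with estimated correlation). Rn7s2, a 7SL RNA gene, was listed at 20799 and 23193 TPM in the shCTR libraries and at 0 in both shE3 libraries. Mir199a-2 went from 5.9 and 9.18 TPM to 0 and Mir214 from 3.19 and 6.89 to 0. Whether reads of these 3 genes were assigned elsewhere in the shE3 libraries was not tested. Car4, which rose most with CD, fell here (-2.40 ± 0.16).

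Rises were fewer: Ugt1a6b (2.17 ± 0.18), Hmga1b (2.15 ± 0.12), Cps1 (1.45 ± 0.17), Mcpt9 (1.45 ± 0.16), Tyrobp (1.44 ± 0.20) and Plek (1.36 ± 0.16). Macrophage markers passed upward as a list, with Lyz2 and Tyrobp, as did p53 and senescence genes and fibroblast genes (Fap 0.78 ± 0.11), though most members did not pass as deposited. Of 13 macrophage markers, 3 rose, 0 fell and 10 did not pass (camera adjusted p = 0.00858, or 0.526 with estimated correlation). Of 26 p53 and senescence genes, 7 rose, 0 fell and 19 did not pass, 12 and 1 relative to the median gene (camera adjusted p = 0.000968, or 0.751 with estimated correlation). Of 33 fibroblast genes, 6 rose, 2 fell and 25 did not pass, 11 and 2 adjusted over the list alone, 16 and 3 relative to the median gene (camera adjusted p = 0.00858, or 0.751 with estimated correlation). Camera was downward for endothelial markers (Flt1 -1.75 ± 0.12) and cholesterol synthesis genes, again with most members not passing as deposited. Of 24 cholesterol synthesis genes, 0 rose, 7 fell and 17 did not pass, 0 and 9 adjusted over the list alone, 0 and 10 relative to the median gene (camera adjusted p = 0.018, or 0.751 with estimated correlation). Of 8 endothelial markers, 0 rose, 3 fell and 5 did not pass (camera adjusted p = 0.00858, or 0.555 with estimated correlation). Lists that did not pass camera included inflammatory mediators (4 rose and 4 fell of 29, 6 and 5 adjusted over the list alone, 10 and 5 relative to the median gene, camera adjusted p = 0.16), with Mmp10 up (0.97 ± 0.10) and Cxcl3 down (-1.01 ± 0.14), interferon-stimulated genes (1 rose and 7 fell of 28, camera adjusted p = 0.094; Oasl2 -1.43 ± 0.18), and the exosome list itself (0 rose and 4 fell of 27, camera adjusted p = 0.145). In all, 761 genes rose and 1934 fell of 15700 tested, with a median gene at -0.04; relative to it 2224 rose and 2186 fell (28.2 and 50.4 percent upward). The count rests on both shE3 libraries: 1749 without shE3 replicate 1 and 1700 without shE3 replicate 2. Without shCTR replicate 2 the balance turns, with 1816 up and 1263 down.

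**Figure D2:**
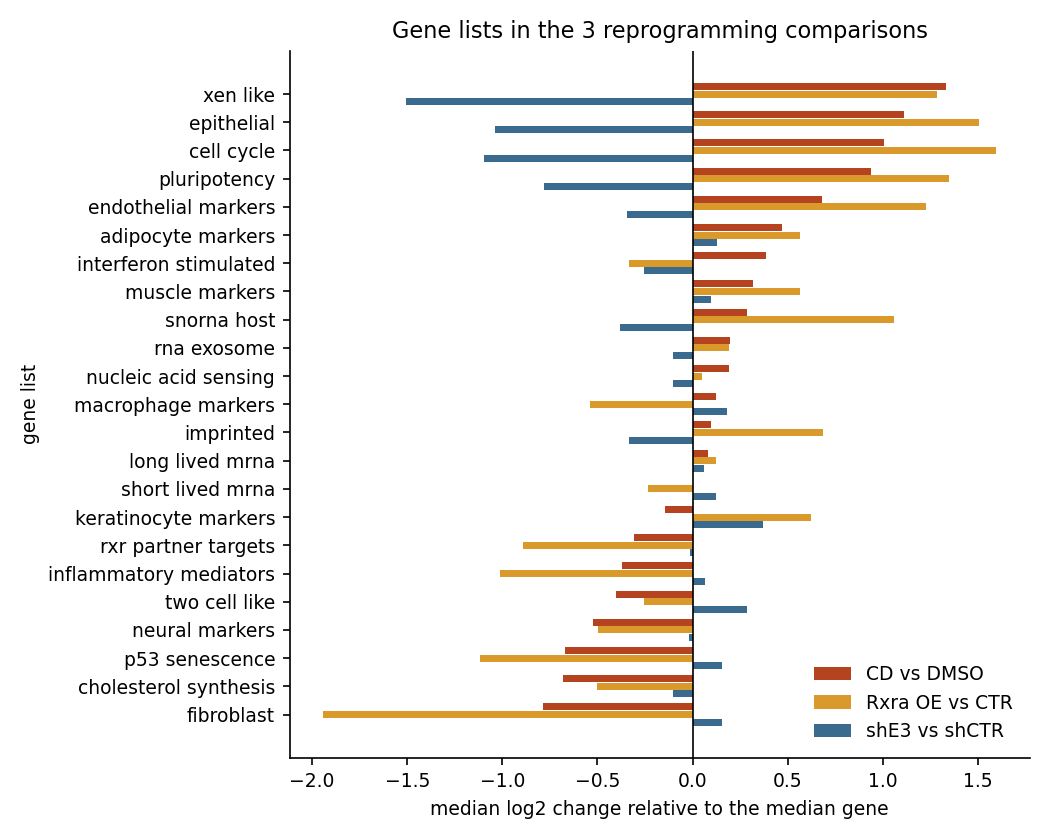
Median log2 change relative to the median gene (horizontal axis) of each fixed gene list (vertical axis) for CD against DMSO, Rxra OE against CTR and shE3 against shCTR (bars, n = 2 libraries per group). XEN-like, epithelial, cell cycle and pluripotency genes lie above 0 with CD and Rxra OE and below 0 with shE3.

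More genes than expected by chance were called in the same direction with CD3254 and Rxra overexpression, and in opposite directions with CD3254 and Exosc3 knockdown; the comparisons share no libraries. Of 12623 genes tested in both tables, 5282 rose with CD and with Rxra OE where 3749.9 are expected by chance (odds ratio 28), and 1420 fell with both where 343 are expected (odds ratio 38.4); both Fisher exact p-values are below the smallest number the software stores. Relative to the median gene the counts are 3005 against 1318 and 3323 against 1426. Only 43 genes rose with CD and fell with Rxra OE, and 258 did the reverse. Of 12705 genes tested in the CD and shE3 tables, 1342 rose with CD and fell with shE3 against 694 expected (odds ratio 8.2, two-sided Fisher exact p = 7.66e-275), and 416 fell with CD and rose with shE3 against 126 (odds ratio 8.87, p = 1.46e-146). In the same direction 35 rose and 94 fell in both. Pearson correlations of the log2 changes across genes were 0.79 for CD and Rxra OE and -0.53 for CD and shE3; genes are not independent replicates.

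Before actinomycin D, which stops transcription, the libraries of a separate table with CD and DMSO showed several of the same changes (CD 0 h against DMSO 0 h, n = 2 per group). Cyp26a1 stood at 1294 ± 64.2 against 489 ± 55.6 CPM (1.24 ± 0.13 relative to the median gene, adjusted p = 0.00116), Tdh at 171 ± 14.3 against 64.5 ± 7.93 CPM (1.23 ± 0.15, adjusted p = 0.00222) and Ccl8 at 229 ± 48.8 against 561 ± 24.4 CPM (-1.47 ± 0.18, adjusted p = 0.00183). Rxra (63 ± 15.1 against 47.3 ± 17.3 CPM, 0.27 ± 0.22, adjusted p = 0.373) did not pass. Nor did Exosc3 (27.7 ± 18.9 against 10.9 ± 5.58 CPM, 1.00 ± 0.42, adjusted p = 0.109), which passes as deposited without CD 0 h replicate 2 (1.90) or DMSO 0 h replicate 1 (1.67).

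Among transcription factor genes, Elf3 (2.78 ± 0.65), Gbx2 (2.63 ± 0.44) and Klf4 (2.03 ± 0.46) rose. These 3 rises are lost without CD 0 h replicate 1 (as deposited 1.83, 2.20 and 1.56) and without DMSO 0 h replicate 2 (2.13, 2.02 and 1.43). Pluripotency genes rose with Tdh and Utf1 (1.29 ± 0.20), while Pou5f1 and Nanog were below 1 CPM in every 0 h library. Of 16 pluripotency genes, 13 rose, 0 fell and 3 did not pass, 15 and 0 adjusted over the list alone (camera adjusted p = 4.83e-07, or 0.415 with estimated correlation). Camera was also upward for cell cycle, XEN-like, epithelial and RNA exosome genes, though most members of each did not pass. Of 32 cell cycle genes, 15 rose, 0 fell and 17 did not pass, 29 and 0 adjusted over the list alone (camera adjusted p = 4.64e-07, or 0.644 with estimated correlation). Of 22 XEN-like genes, 8 rose, 0 fell and 14 did not pass, 10 and 0 adjusted over the list alone (camera adjusted p = 0.0017, or 0.148 with estimated correlation). Of 22 epithelial genes, 8 rose, 0 fell and 14 did not pass, 10 and 0 adjusted over the list alone (camera adjusted p = 0.00122, or 0.644 with estimated correlation). Of 27 RNA exosome genes, 4 rose, 0 fell and 23 did not pass, 7 and 0 adjusted over the list alone (camera adjusted p = 0.00373, or 0.665 with estimated correlation). Krt19 rose by 1.08 ± 0.16, and Isg15 by 0.93 ± 0.21 although interferon-stimulated genes as a list did not pass (3 rose and 0 fell of 39, camera adjusted p = 0.681); both genes are lost without DMSO 0 h replicate 2 (0.95 and 1.01). Short-lived mRNAs, many of them immediate early genes, passed camera upward. Of 39 short-lived mRNAs, 8 rose, 0 fell and 31 did not pass, 31 and 0 adjusted over the list alone (camera adjusted p = 1.57e-06, or 0.665 with estimated correlation). Long-lived mRNAs, higher with CD in the other table, passed camera downward. Of 35 long-lived mRNAs, 1 rose, 1 fell and 33 did not pass (camera adjusted p = 0.000554, or 0.644 with estimated correlation). Mitochondrial genes took 4.93 and 5.18 percent of CPM in the CD 0 h libraries and 6.92 and 9.03 in the DMSO 0 h libraries. The mitochondrial ribosomal RNA mt-Rnr2 fell (654 ± 314 against 2317 ± 1085 CPM, -1.99 ± 0.44), though not without CD 0 h replicate 1 (-1.32 as deposited) or DMSO 0 h replicate 2 (-1.33). Lrat (-2.30 ± 0.34) and Pcdh10 (-1.80 ± 0.14) fell, as they did with CD in the other table. Fibroblast genes fell, with Cdh11 (-1.09 ± 0.14) and Col5a2 (-1.13 ± 0.18), and among inflammatory mediators Mmp13 (-1.65 ± 0.20) and Mmp3 (-1.55 ± 0.16) fell. Of 33 fibroblast genes, 0 rose, 17 fell and 16 did not pass, 1 and 22 adjusted over the list alone, 0 and 21 relative to the median gene (camera adjusted p = 2.40e-13, or 0.148 with estimated correlation). Of 31 inflammatory mediators, 1 rose, 5 fell and 25 did not pass, 5 and 10 adjusted over the list alone, 1 and 8 relative to the median gene (camera adjusted p = 0.000364, or 0.148 with estimated correlation). Of p53 and senescence genes, Igfbp3 (-1.39 ± 0.24) and Ccng1 (-1.05 ± 0.15) fell; camera was downward for this list and for cholesterol synthesis genes, though most members of both did not pass. Of 26 p53 and senescence genes, 1 rose, 6 fell and 19 did not pass, 3 and 8 adjusted over the list alone (camera adjusted p = 0.00988, or 0.644 with estimated correlation). Of 24 cholesterol synthesis genes, 0 rose, 3 fell and 21 did not pass, 0 and 9 relative to the median gene (camera adjusted p = 0.0103, or 0.665 with estimated correlation). Macrophage markers leaned down, with Lyz2 (-1.42 ± 0.28; not passed without DMSO 0 h replicate 2, -0.99). Of 16 macrophage markers, 0 rose, 8 fell and 8 did not pass (camera adjusted p = 5.04e-07, or 0.415 with estimated correlation). In all, 1510 genes rose and 1128 fell of 17064 tested, over a median gene 0.19 higher; relative to it 1163 rose and 1645 fell (57.2 and 41.4 percent upward). On the recovered reads edgeR called 1019 up and 1797 down, DESeq2 2150 and 2039. The count of 2638 moves to 1103 without a filter, 1707 with the replicate block, 294 with spike-in scaling, 472 without CD 0 h replicate 1, 6164 without CD 0 h replicate 2, 4754 without DMSO 0 h replicate 1 and 236 without DMSO 0 h replicate 2.

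After 8 h of actinomycin D, short-lived mRNAs had fallen in both arms and long-lived ones leaned upward (8 h against 0 h, n = 2 per arm and time, relative to the median gene). These contrasts and the difference of decay share the 0 h libraries with the comparison before actinomycin D. Neither list passes camera with estimated correlation in either arm (adjusted p of 0.469 to 0.673). In DMSO, Sall4, a pluripotency transcription factor gene, fell from 26.4 ± 11.6 to 3.0 ± 1.36 CPM (-2.40 ± 0.36, adjusted p = 0.00374), and Klf4 from 105 ± 73.2 to 12.2 ± 7.27 CPM (-2.53 ± 0.46, adjusted p = 0.0064). The fall of Klf4 is lost without DMSO 0 h replicate 1 or DMSO 8 h replicate 1 (as deposited -2.17 and -2.34). In CD, Ccn1 fell from 309 ± 349.6 to 3.37 ± 0.0843 CPM (-5.05 ± 0.98, adjusted p = 0.00349) and Klf4 from 467 ± 274 to 42.3 ± 4.64 CPM (-2.92 ± 0.46). Exosc3 fell in CD (-1.81 ± 0.42, 4.66 against 27.7 CPM). As deposited, Ccn1, Klf4 and Exosc3 in CD changed by -3.85, -2.67 and -1.44 without CD 0 h replicate 1 and by -7.00, -3.94 and -2.89 without CD 0 h replicate 2. In DMSO Exosc3 passed as deposited (-1.50 ± 0.46), not relative to the median gene (-1.16 ± 0.42, adjusted p = 0.0587), nor as deposited without DMSO 0 h replicate 1 (-1.005) or DMSO 8 h replicate 1 (-1.11). Rxra fell in CD (-0.79 ± 0.22), though not without CD 0 h replicate 1 (-0.92 as deposited), and did not pass in DMSO (-0.28 ± 0.22, adjusted p = 0.331) except without DMSO 0 h replicate 2 (-1.07) or DMSO 8 h replicate 2 (-1.03).

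Short-lived mRNAs fell in both arms, in DMSO and in CD, where Hes1 changed by -3.63 ± 0.59 and Socs3 by -2.29 ± 0.33. In DMSO, of 39 short-lived mRNAs, 0 rose, 34 fell and 5 did not pass, 0 and 37 adjusted over the list alone, 0 and 28 relative to the median gene (camera adjusted p = 3.44e-07, or 0.642 with estimated correlation). In CD, of 39 short-lived mRNAs, 0 rose, 37 fell and 2 did not pass (camera adjusted p = 3.46e-08, or 0.673 with estimated correlation). Among the named genes in CD, Cdx2 (-4.32 ± 0.75), Elf3 (-4.16 ± 0.65) and Nfkbia (-3.88 ± 0.70) fell with Ccn1. In DMSO Sox17 (-1.73 ± 0.25), Lif (-1.11 ± 0.17) and Cyp26a1 (-1.11 ± 0.13) fell. Pluripotency genes fell in DMSO, with Lin28a (-1.08 ± 0.16) and Tdh (-1.26 ± 0.15) beside Sall4, and in CD. In DMSO, of 16 pluripotency genes, 0 rose, 13 fell and 3 did not pass (camera adjusted p = 7.70e-06, or 0.469 with estimated correlation). In CD, of 16 pluripotency genes, 0 rose, 15 fell and 1 did not pass (camera adjusted p = 6.35e-05, or 0.673 with estimated correlation). The RNA exosome list leaned down in DMSO and in CD (Exosc4 -1.80 ± 0.34). In DMSO, of 27 RNA exosome genes, 0 rose, 15 fell and 12 did not pass, 0 and 21 adjusted over the list alone, 2 and 9 relative to the median gene (camera adjusted p = 0.000632, or 0.669 with estimated correlation). In CD, of 27 RNA exosome genes, 0 rose, 21 fell and 6 did not pass (camera adjusted p = 0.000624, or 0.673 with estimated correlation). Cell cycle genes fell in DMSO (Ccnb1 -1.19 ± 0.21) and in CD (Cdc6 -2.45 ± 0.40). In DMSO, of 32 cell cycle genes, 0 rose, 27 fell and 5 did not pass, 0 and 30 adjusted over the list alone, 1 and 15 relative to the median gene (camera adjusted p = 1.25e-06, or 0.642 with estimated correlation). In CD, of 32 cell cycle genes, 0 rose, 30 fell and 2 did not pass, 1 and 26 relative to the median gene (camera adjusted p = 2.94e-06, or 0.673 with estimated correlation). Long-lived mRNAs leaned upward in share in DMSO and in CD. In DMSO, of 35 long-lived mRNAs, 4 rose, 1 fell and 30 did not pass, 13 and 0 relative to the median gene (camera adjusted p = 3.44e-07, or 0.469 with estimated correlation). In CD, of 35 long-lived mRNAs, 16 rose, 5 fell and 14 did not pass, 24 and 4 relative to the median gene (camera adjusted p = 1.35e-05, or 0.673 with estimated correlation). Lrat (2.41 ± 0.34) and Sema3e (1.82 ± 0.20) rose in share in DMSO, and in CD the nuclear RNAs Malat1 (3.61 ± 0.73) and Rn7sk (3.87 ± 0.68) and the mitochondrial ribosomal RNA mt-Rnr1 (3.80 ± 0.61). Fibroblast genes leaned upward in share in DMSO and in CD, together with macrophage markers, of which Lyz2 (2.08 ± 0.28), Mrc1 (2.12 ± 0.26) and Laptm5 (2.13 ± 0.28) rose in CD. In DMSO, of 33 fibroblast genes, 10 rose, 2 fell and 21 did not pass, 21 and 2 relative to the median gene (camera adjusted p = 2.28e-07, or 0.206 with estimated correlation). In CD, of 33 fibroblast genes, 20 rose, 3 fell and 10 did not pass, 21 and 5 adjusted over the list alone, 26 and 3 relative to the median gene (camera adjusted p = 1.08e-08, or 0.27 with estimated correlation). In DMSO, of 16 macrophage markers, 2 rose, 0 fell and 14 did not pass, 0 and 0 adjusted over the list alone, 8 and 0 relative to the median gene (camera adjusted p = 3.76e-05, or 0.469 with estimated correlation). In CD, of 16 macrophage markers, 11 rose, 0 fell and 5 did not pass, 14 and 0 adjusted over the list alone, 14 and 0 relative to the median gene (camera adjusted p = 1.08e-08, or 0.428 with estimated correlation). The protease gene Mmp13 rose in share in both (1.52 ± 0.20 and 1.92 ± 0.20). The size of the changes in CD depends on the 0 h libraries. Without CD 0 h replicate 1, Cdx2, Elf3, Nfkbia, Hes1 and Cdc6 changed by -3.33, -3.42, -3.03, -3.03 and -2.20 as deposited and Malat1, Rn7sk and mt-Rnr1 by 2.12, 2.63 and 2.54. Without CD 0 h replicate 2 they changed by -6.02, -5.65, -5.47, -4.97 and -3.42, and by 4.36, 4.65 and 4.30. Lrat in DMSO changed by 2.64 and 1.39 without DMSO 8 h replicates 1 and 2. In DMSO 647 genes rose and 4702 fell (12.1 percent upward) over a median of -0.33, and 2917 and 2309 relative to it (55.8 percent). In CD 2255 rose and 7066 fell (24.2 percent) over -0.34, and 4282 and 4979 (46.2 percent). The count in DMSO, 5349, moves to 2861 without a filter, 445 without DMSO 0 h replicate 1, and 321 without DMSO 8 h replicate 1. In CD, 9321 moves to 4724 without CD 0 h replicate 1 and 6137 without CD 8 h replicate 1.

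Whether CD changes the decay of individual RNAs was tested as the difference between the 8 h changes of the arms (n = 2 per arm and time). One gene passed in limma, the mitochondrial leucine tRNA gene mt-Tl1, whose 8 h change was 2.92 ± 0.22 higher in CD (adjusted p = 0.000716). With spike-in scaling it no longer passes (2.84, adjusted p = 0.0929). Exosc3 (-0.67 ± 0.65, adjusted p = 0.675; 0.06 without CD 0 h replicate 1) and Rxra (-0.46 ± 0.38, adjusted p = 0.61) did not pass. At an unadjusted p under 0.05 there were 1959 genes; edgeR called 1 gene and DESeq2 49, and limma calls 364 without CD 0 h replicate 2, 2 without CD 0 h replicate 1 and 2 without DMSO 0 h replicate 2. At 4 h limma called 0 genes, with 785 at an unadjusted p under 0.05, edgeR 1 and DESeq2 2. In this difference 7 of 23 lists passed camera, not all of them named here. Macrophage markers had the smallest camera adjusted p, upward, as were imprinted genes (adjusted p = 0.000735) and fibroblast genes (0.0038). Short-lived mRNAs (0.00233) and cholesterol synthesis genes (0.00221) went down. No list holds with an estimated correlation (lowest adjusted p = 0.403). Of 16 macrophage markers, 0 rose, 0 fell and 16 did not pass, 4 and 0 adjusted over the list alone (camera adjusted p = 7.70e-06, or 0.403 with estimated correlation). RNAs raised by Exosc3 knockdown, 761 genes of which 733 were tested here, showed no passing difference in their 8 h change under CD (median 0.01, camera p = 0.675, or 0.89 with an estimated correlation). The direction of that test turns downward without CD 0 h replicate 1, DMSO 0 h replicate 2 or DMSO 8 h replicate 2 (camera p of 0.0709, 0.736 and 0.713), and without CD 0 h replicate 2 it passes upward (0.041), as it does with quantile normalization (0.0244). Their 4 h change was higher in CD (median 0.07, camera p = 0.000215), but not with estimated correlation (p = 0.251). RNAs lowered by the knockdown (1668 tested of 1934) had a higher 8 h change under CD, with a median of 0.12 against -0.03 in the other genes (camera p = 0.000556, or 0.337 with an estimated correlation). At 4 h the direction is downward without passing (0.424).

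The internal sequence of the endogenous retrovirus MMVL30 (MMVL30-int) was at 3449 ± 106 CPM in CD and 3208 ± 25 CPM in DMSO before actinomycin D (n = 2 per arm and time; 0.10 ± 0.16, adjusted p = 0.751 over repeat families). As deposited it stood at 2621 ± 253 CPM at 4 h and 2029 ± 115 at 8 h in CD, and at 3313 ± 556 and 2523 ± 127 in DMSO. The 8 h change is -0.77 ± 0.16 in CD (adjusted p = 0.00966) and -0.35 ± 0.16 in DMSO (adjusted p = 0.159), a difference of -0.42 ± 0.22 that does not pass (adjusted p = 0.821). Relative to the median gene the change in CD is -0.39 ± 0.21 (adjusted p = 0.307), and scaled to the spike-ins -1.11 ± 0.19 (adjusted p = 0.0233). With its 4 h and 8 h values exchanged, as its read counts require unless all other values are exchanged instead, the 8 h change is -0.40 ± 0.16 in CD (adjusted p = 0.0885) and 0.04 ± 0.16 in DMSO, and the difference -0.43 ± 0.22 (adjusted p = 0.821). Exchanged, the change in CD passes when scaled to the spike-ins (-0.74 ± 0.18, adjusted p = 0.0272) and not relative to the median gene (-0.02 ± 0.20, adjusted p = 0.969). RLTR6_Mm, an LTR family assigned to the same class, rose in share in CD as deposited (1.11 ± 0.18, adjusted p = 0.00558). Short interspersed elements fell as deposited in 28 of 34 families in DMSO and 30 in CD, but relative to the median gene in 0 and 10 (19 and 25 changed at an unadjusted p under 0.05 in limma), with medians of -0.31 and -0.41.

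**Figure D3:**
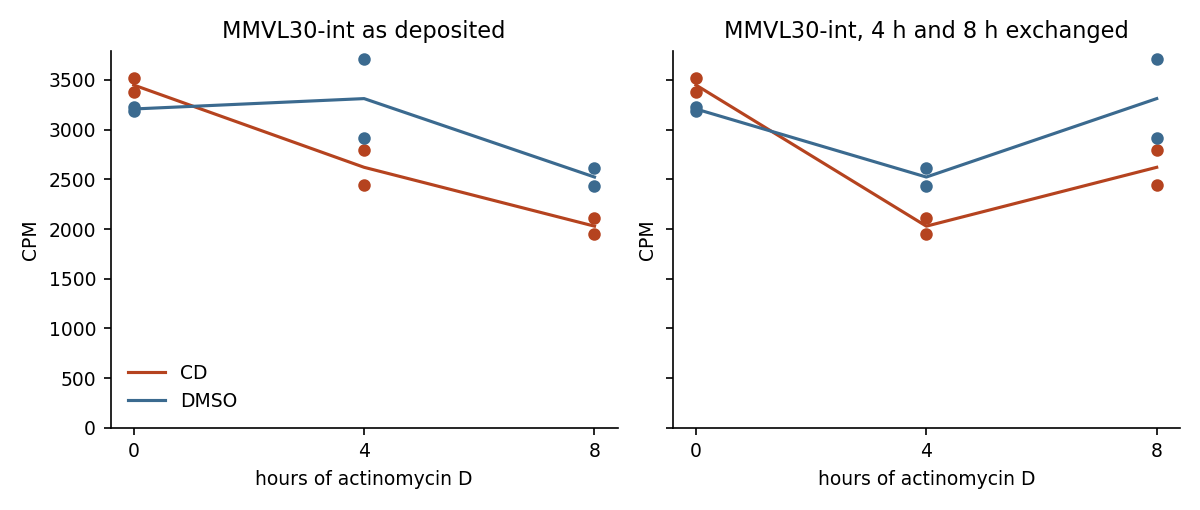
MMVL30-int in CPM (vertical axis) by hours of actinomycin D (horizontal axis) in CD and DMSO, as deposited and with the 4 h and 8 h values exchanged; points are libraries and lines join the means of n = 2. As deposited the CD mean falls from 3449 at 0 h to 2029 at 8 h.

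CD iPSC differed from DMSO iPSC in pluripotency, 2-cell-like, cholesterol synthesis and fibroblast genes (n = 2 per group). The lines per group are not stated, so line and CD effects cannot be told apart. Bnip3, a mitophagy gene induced by hypoxia, stood at 466 ± 64.5 against 28.5 ± 1.28 TPM (3.98 ± 0.12, adjusted p = 5.10e-05), and Myc at 0.811 ± 1.15 against 38.6 ± 1.66 TPM (-4.61 ± 0.40, adjusted p = 0.000407; -5.31 and -3.92 without CD iPSC replicates 1 and 2). Pou5f1 did not pass (1335 ± 279 against 1360.3 ± 121 TPM, adjusted p = 0.873), and Nanog fell (354 ± 6.46 against 598 ± 28 TPM, -0.75 ± 0.13). Rxra fell (5.01 ± 1.8 against 10.5 ± 0.323 TPM, -0.97 ± 0.22, adjusted p = 0.012), but not without DMSO iPSC replicate 1 (-0.998) or DMSO iPSC replicate 2 (-0.94), and Exosc3 did not pass (43.7 against 55.2 TPM, adjusted p = 0.22).

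Beside Bnip3, Cox4i2 (4.23 ± 0.54), Ndufa4l2 (4.21 ± 0.27), Espn (3.85 ± 0.21) and Aldoc (3.72 ± 0.20) rose most; Cox4i2 and Ndufa4l2 encode respiratory chain subunits used under low oxygen. Cox4i2 changed by 4.92 and 3.54 without DMSO iPSC replicates 1 and 2. Tspan18 was listed at 0 in both DMSO iPSC libraries and at 8.7 and 12.8 TPM in the CD iPSC libraries. The glycolytic genes Tpi1 (1.90 ± 0.14) and Pgk1 (1.75 ± 0.11) led the long-lived mRNAs. Of 36 long-lived mRNAs, 16 rose, 4 fell and 16 did not pass (camera adjusted p = 0.00855, or 0.605 with estimated correlation). Cholesterol synthesis genes rose, with Stard4 (1.96 ± 0.14), Insig1 (1.69 ± 0.11) and Cyp51 (1.11 ± 0.08), and so did Scd1 (2.12 ± 0.14). Of 24 cholesterol synthesis genes, 17 rose, 1 fell and 6 did not pass (camera adjusted p = 2.08e-06, or 0.0372 with estimated correlation). 2-cell-like genes fell: Zscan4c stood at 11.1 ± 0.893 against 72.6 ± 1.41 TPM (-2.61 ± 0.13), beside Zscan4d (-2.93 ± 0.16) and Zscan4e (-2.48 ± 0.14). Of 22 2-cell-like genes, 0 rose, 20 fell and 2 did not pass (camera adjusted p = 7.26e-12, or 0.0301 with estimated correlation). Pluripotency genes fell as a list, with L1td1 (-3.08 ± 0.13), Nr0b1 (-2.08 ± 0.11) and Zfp42 (-1.91 ± 0.09). Of 30 tested, 3 rose, 23 fell and 4 did not pass (camera adjusted p = 3.79e-09, or 0.0372 with estimated correlation). Pramel6 (-4.88 ± 0.26) fell as far as Myc, followed by Ube2dnl1 (-4.26 ± 0.30), Spry4 (-3.74 ± 0.17), Enox1 (-3.61 ± 0.17) and Foxd3 (-3.58 ± 0.23). Fibroblast genes fell, with Thbs1 (-1.93 ± 0.10) and Acta2 (-1.85 ± 0.10). Of 33 tested, 0 rose, 26 fell and 7 did not pass (camera adjusted p = 1.03e-10, or 0.0435 with estimated correlation). Short-lived mRNAs, with Id3 (-2.77 ± 0.17) and Dusp6 (-2.53 ± 0.13), and macrophage markers, with C1qa (-2.39 ± 0.26) and Lyz2 (-1.32 ± 0.13), leaned down. Of 39 short-lived mRNAs, 5 rose, 20 fell and 14 did not pass (camera adjusted p = 0.000857, or 0.434 with estimated correlation). Of 18 macrophage markers, 0 rose, 7 fell and 11 did not pass, 1 and 11 adjusted over the list alone (camera adjusted p = 0.00855, or 0.137 with estimated correlation). In all, 3486 genes rose and 3218 fell of 17414 tested; 4202 genes are called without DMSO iPSC replicate 1 and 3981 without DMSO iPSC replicate 2, against 6704.

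Against embryonic fibroblasts (MEF), both kinds of iPSC carried more RNA of pluripotency genes and less of fibroblast genes (n = 2 per group). These contrasts share the MEF and iPSC libraries, so they are not independent. Pou5f1 was listed at 0 in both MEF libraries, at 1275 and 1446 TPM in DMSO iPSC and at 1532 and 1138 TPM in CD iPSC. Dppa5a, also listed at 0 in MEF, was at 2327 and 2319 TPM in DMSO iPSC and 3508 and 3329.5 in CD iPSC, and Tdgf1, at 0 as well, at 649 and 644 and at 905 and 1007. Nanog stood at 598 ± 28 against 0.144 ± 0.203 TPM in DMSO iPSC (9.04 ± 0.13) and 354 against 0.144 TPM in CD iPSC (8.29 ± 0.13); Sox2 rose by 7.41 ± 0.12 and 6.99 ± 0.12, Cdh1 by 5.88 ± 0.13 and 6.11 ± 0.13, and Upp1 by 9.23 ± 0.29 in CD iPSC. The collagen gene Col1a2 fell from 5354 ± 110.2 TPM to 75.5 ± 0.927 in DMSO iPSC (-6.13 ± 0.08, adjusted p = 3.15e-08) and 32.5 ± 0.0959 in CD iPSC (-7.32 ± 0.08, adjusted p = 2.35e-08). Ptn (-9.39 ± 0.17; -9.72 ± 0.17), Aspn (-8.88 ± 0.21; -8.94 ± 0.21), Igfbp5 (-8.28 ± 0.23; -8.52 ± 0.23) and Igf2 (-8.18 ± 0.37; -8.47 ± 0.37) fell most in both, with Mfap4 in DMSO iPSC (-8.25 ± 0.25) and Col3a1 and Ccn3 in CD iPSC (-9.26 ± 0.12; -8.63 ± 0.17). Rxra fell (-1.58 ± 0.22 and -2.55 ± 0.22, from 33.5 TPM in MEF) and Exosc3 rose (1.11 ± 0.19 and 0.78 ± 0.19, from 24.8 TPM).

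By list, in DMSO iPSC and then CD iPSC, pluripotency genes rose and fibroblast genes fell. Of 30 pluripotency genes in DMSO iPSC, 30 rose, 0 fell and 0 did not pass (camera adjusted p = 9.81e-20, or 0.0222 with estimated correlation). Of 30 pluripotency genes in CD iPSC, 28 rose, 1 fell and 1 did not pass (camera adjusted p = 3.94e-16, or 0.0308 with estimated correlation). Among the 33 fibroblast genes in DMSO iPSC, 0 rose, 33 fell and 0 did not pass (camera adjusted p = 2.60e-15, or 0.0222 with estimated correlation). Among the 33 fibroblast genes in CD iPSC, 0 rose, 33 fell and 0 did not pass (camera adjusted p = 1.33e-16, or 0.0308 with estimated correlation). Interferon-stimulated genes fell: Isg15, at 289 ± 45 TPM in MEF, was at 0.845 ± 0.368 in DMSO iPSC. Of 40 interferon-stimulated genes in DMSO iPSC, 0 rose, 37 fell and 3 did not pass (camera adjusted p = 6.47e-12, or 0.0222 with estimated correlation). Of 40 interferon-stimulated genes in CD iPSC, 1 rose, 37 fell and 2 did not pass (camera adjusted p = 1.94e-12, or 0.0308 with estimated correlation). Cell cycle genes rose in 29 and 29 of 32 cases (30 and 0 adjusted over the list alone; 29 and 0 adjusted over the list alone; camera adjusted p = 3.88e-11 and 8.54e-11, or 0.05002 and 0.0604 with an estimated correlation), with Ccne1 (2.81 ± 0.08) in DMSO iPSC and Mcm6 (2.67 ± 0.09) in CD iPSC, and cholesterol synthesis genes fell. Of 24 cholesterol synthesis genes in DMSO iPSC, 0 rose, 21 fell and 3 did not pass (camera adjusted p = 1.34e-06, or 0.0222 with estimated correlation). Among the 24 cholesterol synthesis genes in CD iPSC, 2 rose, 14 fell and 8 did not pass (camera adjusted p = 0.0155, or 0.0977 with estimated correlation). Macrophage markers fell, led by Lyz2 (-4.06 ± 0.13; -5.38 ± 0.13), with inflammatory mediators. Of 18 macrophage markers in DMSO iPSC, 1 rose, 17 fell and 0 did not pass (camera adjusted p = 5.54e-06, or 0.0263 with estimated correlation). Of 18 macrophage markers in CD iPSC, 1 rose, 17 fell and 0 did not pass (camera adjusted p = 1.26e-06, or 0.0308 with estimated correlation). Of 31 inflammatory mediators in DMSO iPSC, 2 rose, 23 fell and 6 did not pass (camera adjusted p = 4.37e-06, or 0.05002 with estimated correlation). Of 31 inflammatory mediators in CD iPSC, 3 rose, 26 fell and 2 did not pass (camera adjusted p = 8.66e-07, or 0.0464 with estimated correlation). 2-cell-like genes rose. Of 22 2-cell-like genes in DMSO iPSC, 21 rose, 0 fell and 1 did not pass (camera adjusted p = 3.47e-09, or 0.0222 with estimated correlation). Of 22 2-cell-like genes in CD iPSC, 14 rose, 0 fell and 8 did not pass (camera adjusted p = 0.000192, or 0.0464 with estimated correlation). Counts were 5465 up and 6303 down in DMSO iPSC, 5802 and 6161 in CD iPSC, of 17414 tested.

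**Figure D4:**
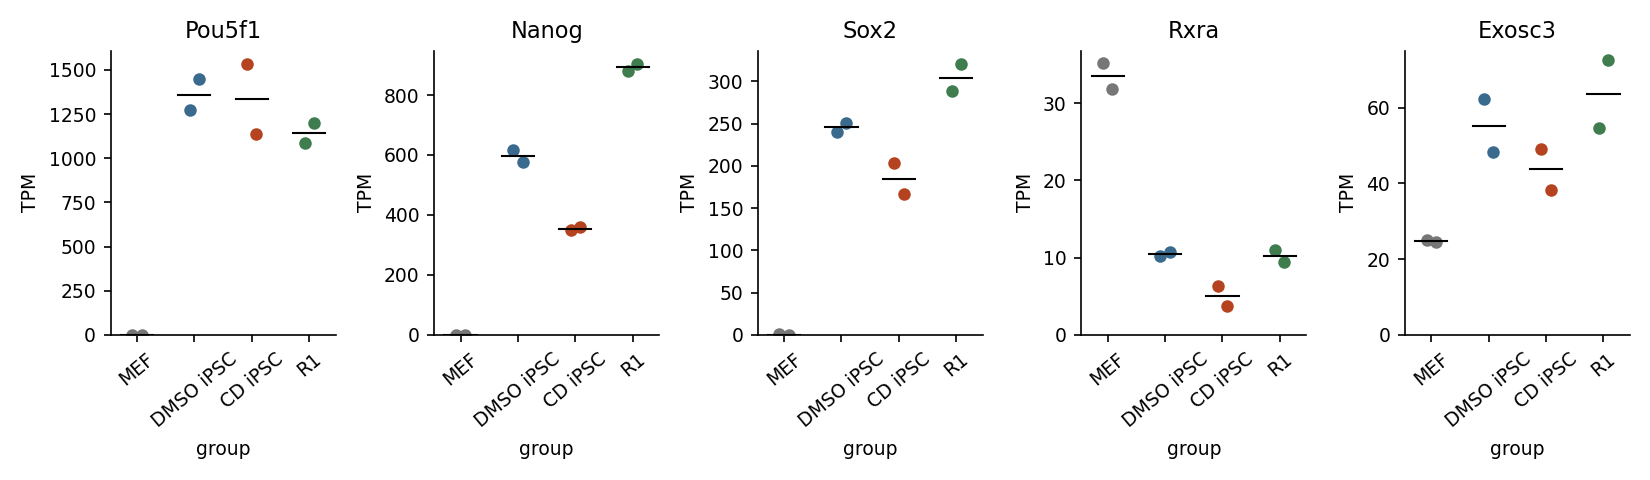
Pou5f1, Nanog, Sox2, Rxra and Exosc3 in TPM (vertical axes) in each library (points) of MEF, DMSO iPSC, CD iPSC and R1 (horizontal axes), with a line at the mean of n = 2. Nanog is at 892 TPM in R1, 598 in DMSO iPSC and 354 in CD iPSC.

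Set against R1 embryonic stem cells (n = 2 per group; the iPSC and R1 libraries are shared with the comparisons above), CD iPSC were low in pluripotency genes and DMSO iPSC were higher in fibroblast genes. With estimated correlation the first list does not pass (adjusted p = 0.0577) and the second does (0.0316). Pou5f1 passed in neither (adjusted p = 0.367 in CD iPSC and 0.0603 in DMSO iPSC; without CD iPSC replicate 2 the first passes, at 0.42), whereas Nanog was lower in CD iPSC (354 ± 6.46 against 892 ± 14.7 TPM, -1.33 ± 0.13, adjusted p = 0.00119), as was Zfp42 (84.8 ± 5.73 against 485 ± 4.65 TPM, -2.50 ± 0.09, adjusted p = 9.75e-05). Thbs1 was higher in DMSO iPSC (133 ± 5.63 against 33.4 ± 0.543 TPM, 2.15 ± 0.10 relative to the median gene, adjusted p = 0.000182). Rxra was lower in CD iPSC (-0.93 ± 0.22, adjusted p = 0.0229), but not without R1 replicate 1 (-0.82) or R1 replicate 2 (-1.03), and did not pass in DMSO iPSC (0.22 ± 0.20). Exosc3 passed in neither (-0.53 ± 0.19 and -0.01 ± 0.18).

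In CD iPSC the pluripotency list fell, with L1td1 (-2.88 ± 0.13) and Klf5 (-2.19 ± 0.11). Of 30 pluripotency genes in CD iPSC, 2 rose, 23 fell and 5 did not pass (camera adjusted p = 1.43e-08, or 0.0577 with estimated correlation). 2-cell-like genes fell, with Zscan4d (-1.96 ± 0.16) and Zscan4c (-1.69 ± 0.13); Pramel6 fell with them (-3.90 ± 0.26). Of 22 2-cell-like genes in CD iPSC, 0 rose, 19 fell and 3 did not pass, 0 and 16 relative to the median gene (camera adjusted p = 1.25e-08, or 0.0553 with estimated correlation). Long-lived mRNAs, with Pgk1 (1.29 ± 0.11) and Eno1 (1.13 ± 0.10), p53 and senescence genes, with Pmaip1 (2.29 ± 0.12), cholesterol synthesis genes, with Insig1 (0.86 ± 0.11), and snoRNA host genes leaned upward, though most members of each did not pass as deposited. Of 14 snoRNA host genes in CD iPSC, 5 rose, 0 fell and 9 did not pass, 7 and 1 adjusted over the list alone, 8 and 0 relative to the median gene (camera adjusted p = 0.00152, or 0.202 with estimated correlation). Of 36 long-lived mRNAs in CD iPSC, 12 rose, 1 fell and 23 did not pass, 15 and 1 adjusted over the list alone, 17 and 0 relative to the median gene (camera adjusted p = 6.32e-07, or 0.386 with estimated correlation). Of 26 p53 and senescence genes in CD iPSC, 7 rose, 1 fell and 18 did not pass (camera adjusted p = 0.00187, or 0.129 with estimated correlation). Among the 24 cholesterol synthesis genes in CD iPSC, 6 rose, 0 fell and 18 did not pass, 9 and 0 relative to the median gene (camera adjusted p = 0.0124, or 0.178 with estimated correlation). The apolipoprotein gene Apoa2 was listed at 0 in both R1 libraries, at 19.1 and 16.3 TPM in CD iPSC and at 14.7 and 20.0 in DMSO iPSC. Apoc2 was at 0 in R1 and 12.8 and 11 in CD iPSC. Dppa3, a germ line and naive pluripotency gene, was higher in both (2.98 ± 0.27 and 3.07 ± 0.27), and Dll1 in CD iPSC (3.21 ± 0.25). Mir692-2 was lower in both (-4.12 ± 0.29 and -3.91 ± 0.28). In DMSO iPSC fibroblast genes rose, with Acta2 (2.02 ± 0.10) and Col1a2 (1.56 ± 0.08), and macrophage markers, with Lyz2 (2.48 ± 0.14) and Ctss (2.13 ± 0.21), and 2-cell-like genes leaned upward. Of 22 2-cell-like genes in DMSO iPSC, 10 rose, 0 fell and 12 did not pass, 12 and 0 adjusted over the list alone (camera adjusted p = 1.14e-07, or 0.0316 with estimated correlation). Among the 33 fibroblast genes in DMSO iPSC, 23 rose, 0 fell and 10 did not pass, 27 and 0 adjusted over the list alone, 26 and 0 relative to the median gene (camera adjusted p = 1.87e-20, or 0.0316 with estimated correlation). Of 18 macrophage markers in DMSO iPSC, 7 rose, 0 fell and 11 did not pass, 9 and 0 adjusted over the list alone (camera adjusted p = 2.38e-06, or 0.0316 with estimated correlation). Cholesterol synthesis genes fell there, with Msmo1 (-1.21 ± 0.15) and Stard4 (-1.07 ± 0.16). Among the 24 cholesterol synthesis genes in DMSO iPSC, 0 rose, 15 fell and 9 did not pass, 0 and 19 adjusted over the list alone, 0 and 12 relative to the median gene (camera adjusted p = 5.09e-06, or 0.0316 with estimated correlation). Ppbp was at 0 in R1 and 9.33 and 12.7 TPM in DMSO iPSC, and Serpina3m rose (3.13 ± 0.38). Counts against R1 were 1295 up and 2839 down in CD iPSC (31.3 percent upward; 1800 and 2171 relative to a median gene at -0.09, 45.3 percent) and 1101 and 2567 in DMSO iPSC (30.02 percent; 1622 and 1257 relative to -0.13, 56.3 percent). Without R1 replicate 1 they are 1805 and 995, without R1 replicate 2 1489 and 993, and in DMSO iPSC 1148 without DMSO iPSC replicate 1 and 827 without DMSO iPSC replicate 2.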

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

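The test of the difference in 8 h change between CD and DMSO, planned before the data were examined, singled out 1 gene and 4 repeat families as changing unequally in the arms (n = 2 per arm and time); apart from the share of mt-Nd4l, the tests that weigh the patterns below were chosen only after the result was seen. The mitochondrial leucine tRNA gene mt-Tl1 differed by 2.92 ± 0.22, adjusted p = 0.000716: it went from 107 ± 15.9 CPM at 0 h to 47.9 ± 0.885 at 4 h and 129 ± 4.52 at 8 h in CD, and from 125 ± 13 to 16.6 ± 0.576 and 19.1 ± 3.11 in DMSO. The families were L1MEg (1.66 ± 0.19, adjusted p = 0.00204) and L1Md_A (2.26 ± 0.40, adjusted p = 0.0329), which are long interspersed elements, the DNA transposon FordPrefect (1.48 ± 0.20, adjusted p = 0.00414) and the retroviral MTEb-int (2.85 ± 0.53, adjusted p = 0.0361). All 5 were higher in CD. Relative to the median gene mt-Tl1 (adjusted p = 9.37e-05), L1MEg (0.00213) and FordPrefect (0.0105) still pass, while L1Md_A and MTEb-int do not (both 0.0776). With spike-in scaling mt-Tl1 (0.0929), L1MEg (0.117) and FordPrefect (0.13) do not pass, while L1Md_A (0.0343) and MTEb-int (0.0384) do. No biological explanation for them was tested.

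The counts of MMVL30-int at 4 h and 8 h do not belong to the libraries they stand under. In 8 of 8 values, whole reads are obtained only with the library of the other time in the same arm and replicate, and the library totals reach 1000000 only with the exchange, so an exchange of this 1 family's times fits. Whether instead all the other genes and families carry exchanged times cannot be told apart from this, because the read grid reads the same either way. Short-lived mRNAs relative to long-lived ones were higher at 8 h than at 4 h (38 of 39 in CD, median 0.91, and 39 in DMSO, median 0.543), which an exchange of all other values may explain, while spike-ins took more CPM at 8 h (1938 ± 99.3 against 1722 ± 111 in CD, 2150.0 ± 42.9 against 1803 ± 138 in DMSO), the reverse of what it would give if they were added per cell, which the labels do not state. If every other value is exchanged, the changes given at 8 h are those at 4 h; renewed transcription late under actinomycin D stays open as an untested biological explanation.

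More genes were higher than lower with CD and with Rxra OE as deposited. A different share of mt-Nd4l alone (45 ± 0.169 percent with CD against 47.6 ± 1.24, 42.4 ± 0.0627 with Rxra OE against 51.1 ± 1.65) is argued against as the whole cause: without mt-Nd4l 75.4 percent of calls with Rxra OE and 62.4 percent with CD were still upward. Shares taken by transcripts outside nuclear coding and lncRNA genes cannot be told apart from a rise of those genes themselves. Rescaled to them, 57.6 percent with Rxra OE and 49.1 percent with CD were upward, but this centres nearly the genes that are tested, as median ratio rescaling does (49.7 and 49.5 percent). A higher content of messenger RNA per cell with CD or Rxra OE stays open as an untested biological explanation, since TPM fixes the total.

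Short-lived mRNAs were higher with CD before actinomycin D, 39 of 39 above 0 with a median of 1.41 ± 0.12 (SE over genes) as deposited. Without CD 0 h replicate 1 the median was 0.668 with 38 above 0. That leaves 1 CD library, so replicate 1 alone stays open. Within numbers 1 and 2 the medians were 1.45 and 1.37. This does not test whether the numbers were handled apart, since each holds both arms. An effect of CD on these genes and a difference in the handling of CD and DMSO cultures may each give the pattern, and both stay open; the first is untested.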

How the results depend on the processing

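Of 4075 values of 292 gene results under the alternatives, 3957 kept direction and side of the threshold, 101 no longer passed, 11 newly passed and 6 turned direction; where a result changed, the cause was not tested. A fold change of at least 2 leaves 1151 for CD, 4192 for Rxra OE, 602 for shE3, 1050 for CD at 0 h, 2661 for 8 h in DMSO, 4679 for 8 h in CD, 3006 for CD iPSC against DMSO iPSC, 1617 for CD iPSC against R1 and 1332 for DMSO iPSC against R1. Without a filter the counts are 2 for shE3, 1103 for CD at 0 h and 2861 for 8 h in DMSO, and with quantile normalization 4061 for shE3 and 3171 for 8 h in DMSO. Median ratio rescaling gives 4410 for shE3. The replicate block gives 1707 for CD at 0 h; fluctuations shared by replicate number between groups correlate at -0.11 for CD, -0.14 for Rxra OE and 0.08 for shE3 across genes, from -0.69 (CD 0 h with DMSO 8 h) to 0.54 (CD 0 h with DMSO 0 h) in the actinomycin D table and from -0.13 to 0.06 in the iPSC table, genes not being independent replicates, and the block changed no call of a named gene. The single gene in the difference of decay becomes 3 with a pseudocount of 0.1 and 2 with eBayes without trend. Chosen after seeing the data, rescaling to nuclear coding and lncRNA genes gives 4382 for shE3, spike-in scaling 294 for CD at 0 h, 3192 for 8 h in DMSO and 0 for the difference of decay, and DESeq2 4189 for CD at 0 h and 49 for the difference of decay; with spike-in scaling 10 of 55 named genes no longer pass. The shE3-raised set passes with quantile normalization (camera p of 0.0244) and at 4 h (0.000215). The shE3-lowered set, looked at after seeing the data, passes in every alternative except an estimated correlation (0.337) and 4 h (0.424, downward). Of 123 list results past camera, 20 remain with an estimated correlation. Leaving out 1 library, with the lone sample assumed to vary like the other groups, gives 6686 to 7329 for CD, 8909 to 10768 for Rxra OE, 1700 to 3079 for shE3, 236 to 6164 for CD at 0 h, 321 to 6622 for 8 h in DMSO, 4724 to 9852 for 8 h in CD, 1 to 364 for the difference of decay, 3981 to 6491 for CD iPSC against DMSO iPSC, 9245 to 10250 for DMSO iPSC against MEF, 9532 to 11558 for CD iPSC against MEF, 1489 to 3794 for CD iPSC against R1 and 827 to 1148 for DMSO iPSC against R1, and 0.041 to 0.736 for the p of the raised set, which turns downward without CD 0 h replicate 1 (0.0709), DMSO 0 h replicate 2 (0.736) and DMSO 8 h replicate 2 (0.713). Named genes that did not pass turned direction when 1 library was left out. As deposited, they are Exosc3 in the difference of decay, -1.39 to 0.0629 (the highest without CD 0 h replicate 1), and Exosc3 and Rxra in DMSO iPSC against R1. There, as deposited, Exosc3 ranged over -0.399 to 0.00448 and Rxra over -0.0619 to 0.147 (the highest for Exosc3 and the lowest for Rxra without R1 replicate 2). Pou5f1 ranged over -0.254 to 0.174 between iPSC lines, turning without CD iPSC replicate 2 or DMSO iPSC replicate 2 (0.0511), and over -0.00429 to 0.424 in CD iPSC against R1, turning without CD iPSC replicate 1. A second unit was not run, since no table holds both FPKM and TPM. Limma recovered the fewest planted 2-fold changes in the difference of decay.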

Other observations

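The CD table and the 0 h libraries of the actinomycin D table share no libraries, and the genes called in both moved alike; this overlap was among the tests chosen only after the result was seen. Of 12723 genes tested in both, 1162 were higher with CD in both where 545 are expected by chance (odds ratio 19.1), and 787 lower in both where 190.2 are expected (odds ratio 25.9); the log2 changes correlate at 0.53 across genes, which are not independent replicates. Cyp26a1 (CD 2.05 ± 0.03; 0 h 1.24 ± 0.13) and Tdh (2.48 ± 0.04; 1.23 ± 0.15) rose in both, and Lrat (-2.49 ± 0.08; -2.30 ± 0.34), Pcdh10 (-2.59 ± 0.06; -1.80 ± 0.14) and Ccl8 (-1.28 ± 0.03; -1.47 ± 0.18) fell in both.

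The fall of repeat families after 8 h of actinomycin D depends on the scaling. As deposited, long terminal repeat (LTR) families fell in 23 and rose in 2 of 401 cases in DMSO, and fell in 72 and rose in 9 in CD; relative to the median gene limma called 0 in DMSO, with 41 at an unadjusted p under 0.05, and in CD they fell in 2 and rose in 13. Long interspersed element families fell as deposited in 11 of 122 cases in DMSO and 15 in CD, where 4 rose, and relative to the median gene in 1 and 1, with 8 rising in CD. Before actinomycin D limma called 0 of 656 families between CD and DMSO as deposited (1 relative to the median gene), with 106 at an unadjusted p under 0.05; the count tools were run on genes.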
